A study of Mus musculus with 2 samples.

How the data were processed

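The series holds RNA sequencing of liver from 1 female C57BL/6J mouse aged 10 weeks, as 2 libraries labelled as technical replicates of biological replicate 1. Per the labels, RNA was extracted with a QIAGEN kit for lipid-rich tissue, polyA RNA was selected, the size range was 350 to 450 with no unit stated, and library 2 was performed in May 2015. Both libraries form 1 group, so no groups were compared. No sex, age, diet or tissue comparison was possible. A library difference and a difference in date or handling cannot be told apart in this design.

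For each library the authors deposited a gene table and a transcript table. The deposited expected counts are estimated read or fragment counts per gene or transcript and are not normalised. The deposited TPM values are length-normalised relative abundances over all annotated genes or transcripts, and sum to the same total in each library. The deposited FPKM values are normalised to length and to the number of fragments. The deposited isoform shares are in percent of the gene's TPM. Per the file headers and descriptions, the values rest on alignments to mm10 with annotation M4. The quantification tool, the aligner and the strandedness of counting are not given in the sources used here, although the column names are those RSEM writes. The expected counts sum to 23309905 in library 1 and 19525500 in library 2. Of 69691 entries in the gene table, 97 spike-in entries and 26248 with a numeric identifier had a sum of 0 in both libraries.

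Symbols, biotypes, coordinates and transcript sequences were taken from GENCODE M21, a later annotation of the same assembly (GRCm38). Of 43346 Ensembl genes, 42462 had a symbol there. Genes with no symbol held 0.0721% of counts in library 1 and 0.0663% in library 2. Transcript GC content was taken where the M21 length lay within 10% of the deposited length (97772 of 103639 transcripts, 91424 of them with the same length). That tolerance was loosened after exact lengths were seen to cover too few genes. A gene's GC content is the mean over its transcripts weighted by TPM summed over the libraries. A nuclear gene counted as a copy of mitochondrial sequence when at least 50% of its 25-base words occurred in the mitochondrial genome, which marked 9 genes.

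A gene counted as detected at a TPM of at least 1. Levels on the log scale are log2(TPM + 0.1). For the comparison of the libraries, expected counts were rounded, genes with a summed count of at least 20 were kept, and counts were scaled with TMM in edgeR (factors 0.818 and 1.22). The log2 fold is library 2 over library 1 with a prior count of 0.5. The quasi-likelihood test of edgeR has no residual degrees of freedom with 1 library on each side, so each gene had a two-sided exact binomial test of its counts, with Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05 and a log2 fold of at least 1 in size. Intervals of folds are exact binomial intervals at 95%. Where a library had 0 counts, the fold is a bound against 3 counts in that library. Such a bound covers counting error only, not the division of shared reads between genes. The coefficient of variation is the square root of the common dispersion from edgeR. Sampling error was simulated with a fixed seed.

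A set of 34 gene lists, covering liver functions, other cell types and tissues, sex and mitochondria, was fixed before the data were examined, as were the tests, the thresholds, most of the other settings tried and the rule for naming genes. Each list's median fold was placed among 10000 random lists of the same size matched on mean expression in 50 bins. The listed symbols Hbb-b1, Hbb-b2, Ahsp, Snhg1 and Hjv had no match. Some genes are in more than 1 list, and the lists for other tissues hold genes that liver expresses. The rule named the 25 nuclear protein-coding genes with the highest mean TPM, up to 6 of the highest and up to 2 undetected members of each list, the 10 largest differences in each direction among called genes with a TPM of at least 5 in the higher library, and the 10 largest changes of isoform share. Not every gene under the rule is named in the text. Fasn, Apob, Ttr, Mup13, Mki67, Moxd1, Prss1, Prss2, Cpa1, Usp9y and Sry lie outside it and were chosen after their values were seen. So were the isoforms of Apoe and Apoa1, and the genes named in the last section where it says so.

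The isoform comparison covered genes with at least 2 annotated transcripts, a mean TPM of at least 10 and a TPM above 0 in both libraries. The last condition was an addition to the planned comparison. Shares of genes carry exact Clopper-Pearson intervals. After the data were seen, a loess curve of fold on GC content (span 0.3), fitted on nuclear genes, was subtracted from the folds of 12128 genes with a GC value, and the comparison was repeated without mitochondrial genes and their copies. Values of some genes, including Apoe and mitochondrial genes, had been seen during the check of units, before the predictions for the tests of explanations were written.

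The calling procedure was tested on simulated counts with sampling error alone and no further variation between libraries. Its false calls therefore give no error rate for the real libraries. Of 200 genes raised or lowered by a log2 fold of 1.5, 92.5% were called, with 2 false calls among 11997 tested genes. With a simulated linear GC trend added and the curve subtracted, 87.4% of 198 were called, with 1 false call. At a log2 fold of 3, 99.5% of 200 were called, with 0 false calls. Other settings changed the scaling, the count minimum, the pseudocount or prior count, the unit, the gene set, the list summary and the isoform thresholds, and left out each library in turn. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.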

Results

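RNA selected for polyA tails was measured in the liver of 1 adult female mouse of the C57BL/6J inbred strain, aged 10 weeks. The series holds 2 libraries of that animal, labelled as technical replicates 1 and 2 and called library 1 and library 2 here. The labels date library 2 to May 2015 and give no date for library 1. The deposited gene tables sum to 23309905 expected counts in library 1 and 19525500 in library 2. There is no second animal, sex, tissue or treatment in the series, so the data answer 2 questions: how abundant each transcript was in this liver, and how far the 2 libraries of the same animal differed. Every mean and SD below is over the 2 technical libraries (n = 2) and measures technical spread, not variation between animals.

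Genes for secreted plasma proteins, lipid carriers, major urinary proteins and drug-metabolising enzymes made up most of the highest nuclear transcripts of this liver. Alb, which codes for serum albumin (ENSMUSG00000029368.9, chromosome 5, 90460897 to 90476602, plus strand), was the highest nuclear protein-coding gene, at 22689.5 TPM, the deposited length-normalised abundance, in library 1 and 49848 in library 2 (mean 36269 ± 19204, SD). Apoe, an apolipoprotein of circulating lipoproteins (ENSMUSG00000002985.11, chromosome 7, 19696109 to 19699188, minus strand), came next by mean (11052 ± 15111), but from 367 TPM in library 1 and 21738 in library 2. Apoa2, the second major protein of high-density lipoprotein, read 3002 and 18343 TPM, and Trf, the iron carrier transferrin, 6160.0 and 10699. Mup10, a major urinary protein gene (ENSMUSG00000078680.3, chromosome 4, 60578260 to 60582199, minus strand), ran the other way, with 11414 TPM in library 1 and 5345 in library 2. The apolipoprotein gene Apoc1 (1517 and 13547 TPM), the fatty acid binding protein gene Fabp1 (2625 and 8641), the fetuin gene Ahsg (2005 and 8654) and the selenium carrier Selenop (5076 and 5319) followed.

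The rest of the 25 highest nuclear protein-coding genes by mean TPM held mostly the same kinds of gene, apart from Bhmt, B2m and Eef1a1. The microsomal glutathione transferase Mgst1 read 4356 and 5615 TPM, and the serine protease inhibitor genes Serpina3k 3588 and 6298, Serpina1b 2088 and 7340.4, Serpina1c 1812 and 6538, Serpina1a 1895 and 4769, and Serpina1d 1369.8 and 4831. The vitamin D binding protein gene Gc read 4163 and 4718 TPM, the ethanol-oxidising enzyme gene Cyp2e1 3731 and 5139.97, Cyp3a11, a steroid- and drug-oxidising enzyme, 5094 and 3438, and the betaine-homocysteine methyltransferase Bhmt 2687 and 3649. Apoc3, an inhibitor of lipoprotein lipase, read 416 and 6429.7 TPM, and Apoa1, the main protein of high-density lipoprotein, 906 and 5424. Mup3 (5359 and 4029 TPM), Mup14 (3906 and 1594), the class I light chain gene B2m (3476 and 2688) and the translation elongation factor gene Eef1a1 (1378 and 4004) completed the set. The Serpina1 and Mup genes are near-identical paralogs whose shared reads an estimator has to divide, so their single values are uncertain.

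**Figure D1:**
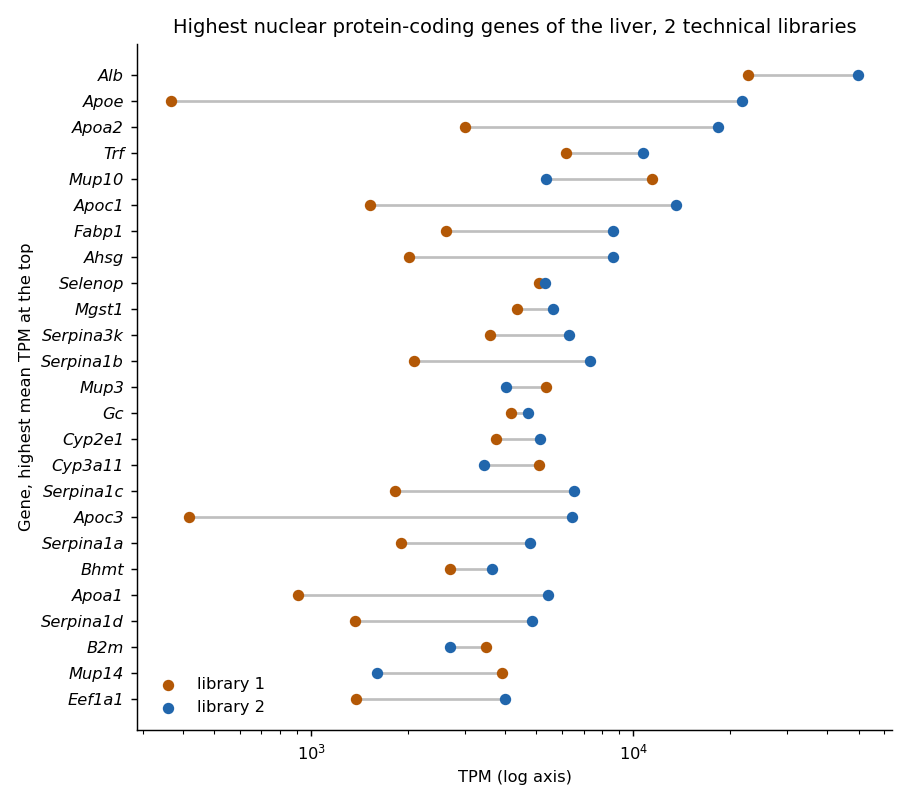
TPM (log axis) of the 25 nuclear protein-coding genes with the highest mean, 1 point per technical library joined by a line. Alb was highest by mean, at 22689.5 TPM in library 1 and 49848 in library 2, and Apoe showed the widest gap, at 367 and 21738.

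Mitochondrially encoded transcripts took 40.7% of all TPM in library 1 and 14.9% in library 2 (mean 27.8 ± 18.3%, SD), and 26.4% and 7.67% of all counts. By TPM, mt-Atp8, a short subunit gene of ATP synthase, was highest at 143799 and 60165, from 130518 and 37163 counts against 2331893 and 647227 of mt-Co1; its TPM rests on a length correction. Next by TPM came the cytochrome oxidase subunit mt-Co1 (75114 and 30899 TPM), cytochrome b, mt-Cytb (37416 and 14784), and the NADH dehydrogenase subunits mt-Nd2 (32467 and 9645), mt-Nd4 (28261 and 10305) and mt-Nd1 (21888 and 8293). A further 9 nuclear pseudogenes that copy mitochondrial sequence brought the share to 61.8% of TPM in library 1 and 25.3% in library 2; reads of a mitochondrial gene and its copy cannot be told apart with certainty. Nuclear protein-coding genes held the remaining bulk, 37.6% of TPM in library 1 and 73.7% in library 2. The 10 highest genes of each library, mitochondrial ones and their copies included, took 52.5% of TPM in library 1 and 27.9% in library 2 (mean 40.2 ± 17.4%, SD). Within nuclear protein-coding genes alone, the top 10 took 19.1% in library 1 and 20.6% in library 2. The 30 secreted plasma protein genes took 6.54% of all TPM in library 1 and 19.95% in library 2 (mean 13.2 ± 9.48%, SD), and 17.4% and 27.1% of the TPM of nuclear protein-coding genes.

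At a TPM of at least 1, 9089 genes were detected in library 1 and 11371 in library 2, of which 8854 were detected in both, 8469 of them protein-coding. Another 235 genes passed in library 1 only (median transcript GC content 42.5%) and 2517 in library 2 only (median 56.1%). Detection by GC content was taken over nuclear protein-coding genes with a GC value and at least 1 count in either library. In library 2 it lay between 61.5% and 70.8% in every class of GC content. In library 1 it ran from 72.7% of these genes at 40 to 45% GC down to 34.7% at 55 to 60% and 12.9% at 60% and over. Fasn, the fatty acid synthase gene with 58.8% GC, read 2.63 TPM in library 1 and 175.6 in library 2, and was chosen as an example after its values were seen.

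**Figure D2:**
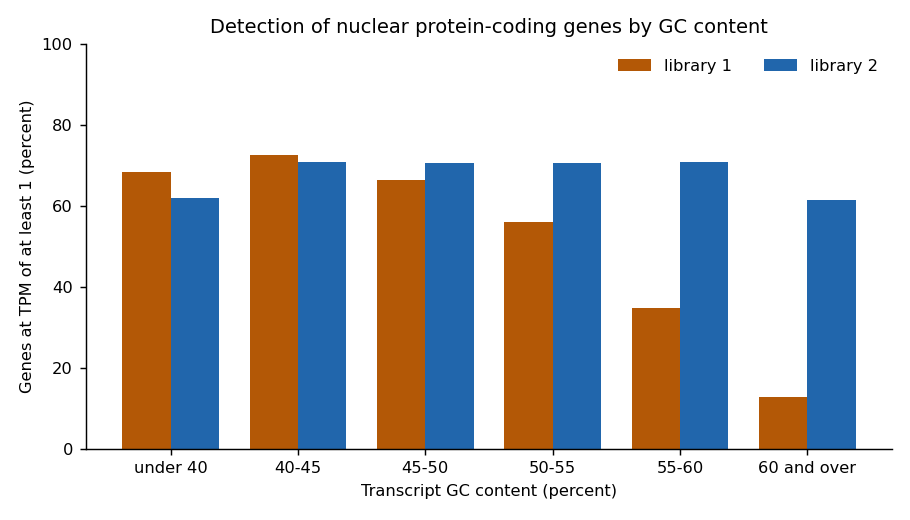
Percent of nuclear protein-coding genes at a TPM of at least 1 (bars, from 0) by transcript GC content (percent), 1 bar per technical library. Only genes with a GC value and at least 1 count in either library are included. Library 1 fell short of library 2 in the GC-rich classes, with 12.9% against 61.5% at 60% and over, and was slightly above it under 40% GC, with 68.3% against 62.0%.

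The animal was labelled female. Xist, the long noncoding RNA that coats the inactive X chromosome, read 192 TPM in library 1 and 125 in library 2, from 44000 and 17355 counts. Of the 8 Y-linked genes, Eif2s3y had 1 count in library 1 and none in library 2, and Ddx3y, Kdm5d, Uty, Zfy1, Zfy2, Usp9y and Sry had 0 counts in both. A count of 0 allows up to 3 counts, which is 0.0495 TPM of Ddx3y in library 1 and 0.0733 in library 2. Female-biased liver genes were abundant: the steroid-oxidising Cyp3a41a read 1415 and 784 TPM, Cyp2c40 940.4 and 796, Cyp2c69 785 and 699, the fatty acid hydroxylase gene Cyp4a10 711 and 901, the bile acid and steroid sulfotransferase gene Sult2a2 713 and 556, and the hepcidin paralog Hamp2 542 and 2651. Some male-biased genes read low, with the fatty acid hydroxylase Cyp4a12a at 0.55 and 0.53 TPM, Cyp4a12b at 0.16 and 0.35 and Moxd1 at 0 counts, while Cyp2c29 (1791 and 1536 TPM), Mup20 (415 and 301), the nudix hydrolase Nudt7 (362 and 376), the glucuronosyltransferase Ugt2b1 (423 and 244), the glutathione transferase Gstp1 (18.1 and 316) and Serpina1e (82.4 and 213) were well above 1. The median log2(TPM + 0.1) of the female-biased list exceeded that of the male-biased list by 3.25 in library 1 and 2.54 in library 2 (mean 2.89 ± 0.50, SD). Without members under 1 TPM in both libraries, that gap was 1.93. Both lists were high among random lists of genes with a count: the male-biased median lay at the 98.1st percentile in library 1 and the 99.3rd in library 2, and the female-biased median above every random list in both. No male sample was measured, so the gap describes this liver and is not a sex comparison.

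The difference between the 2 libraries was large and followed the GC content of the transcripts. Apoe was 19.3-fold higher in library 2 after scaling (log2 fold 4.27, 95% counting interval 4.24 to 4.30), Apoc3 8.12-fold, Apoa1 5.14-fold, Apoc1 4.77-fold and Apoa2 3.57-fold. Mup14 was 4.56-fold lower in library 2 (log2 fold −2.19), Mup10 3.98-fold lower (−1.99), Cyp3a11 2.74-fold lower (−1.46) and B2m 2.41-fold lower (−1.27), while Alb moved by 0.25 and Serpina3k by −0.08 on the log2 scale and were not called. Of 12728 genes with a summed count of at least 20, 7165 (56.3%) were called, 4152 higher and 3013 lower in library 2, at a Benjamini-Hochberg adjusted p under 0.05 in an exact binomial test of the 2 counts and a log2 fold of at least 1 in size. The test compares the reads of these 2 libraries and not conditions, and its intervals cover counting error only. The median log2 fold was 1.15 in size, against 0.083 where sampling alone was simulated, in which 0 genes were called. The technical coefficient of variation was 76.5%, and across genes, which are not independent replicates, log2(TPM + 0.1) of the 2 libraries correlated with Pearson's r of 0.797 and Spearman's rho of 0.771.

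The direction of single genes depends on the scaling. The folds above are scaled by trimmed mean of M-values (TMM); scaling by total count moves every log2 fold by 0.58 toward library 2, and ratios of TPM move the median by 0.80, so genes with a small negative fold change sign. Gc, at a log2 fold of −0.71 (not called), read 4163 and 4718 TPM. Under total-count scaling, 5325 genes were higher and 946 lower in library 2 (84.9% higher, against 57.9% with TMM). Across 12128 tested genes with a known GC content, log2 fold and GC correlated with Spearman's rho of 0.908. A gene's GC content was weighted by the TPM of its transcripts in these same libraries, so it is not independent of the fold. How far that weighting raised the correlation was not tested. Genes higher in library 2 had a median GC of 55.8%, those lower 42.4% and those not called 48.8%. Under 40% GC, 590 of 620 genes were lower in library 2 (median log2 fold −1.71), and at 60% GC and over 392 of 411 were higher (median 4.13). Subtracting a smooth curve of fold on GC, a step added after the data were seen, gave 1708 calls (817 higher, 891 lower) against 6832 without it, and a median size of 0.37.

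**Figure D3:**
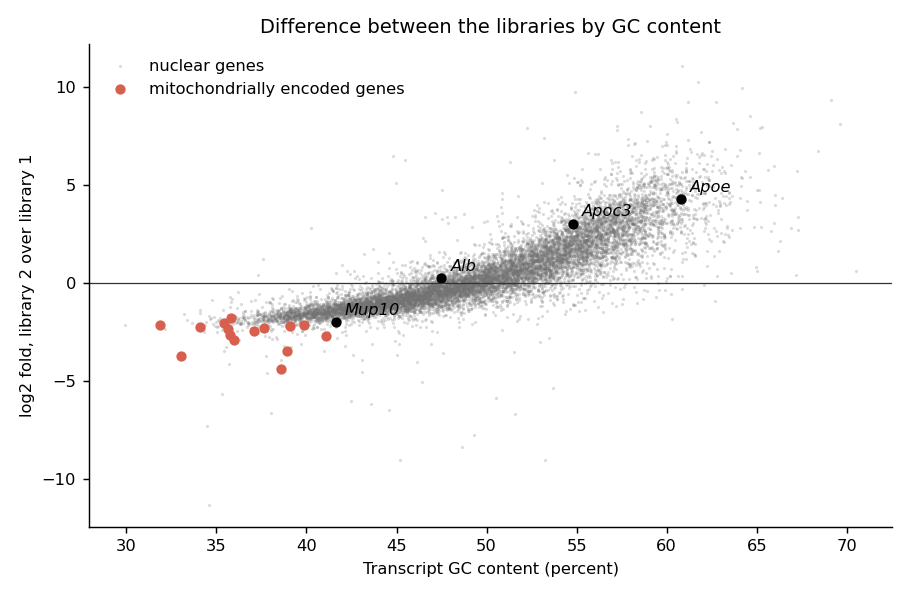
Log2 fold of library 2 over library 1 (TMM scaling) against transcript GC content in percent, 1 point per tested gene. The fold climbed with GC (Spearman's rho 0.908), from Mup10 at −1.99 through Alb at 0.25 to Apoe at 4.27; the 15 mitochondrially encoded genes (red) were lower in library 2 under TMM, DESeq2 and total-count scaling.

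Plasma protein and acute phase genes showed how the libraries parted within 1 function. In brackets, calls in each list are given as higher and lower under the other scaling and after the GC curve, the latter for members with a GC value. Of the 30 secreted plasma protein genes tested, 15 were higher in library 2, 1 was lower and 14 were not called (19 and 0 called under total-count scaling, 2 and 1 after the GC curve), with a median log2 fold of 1.03, above all of 10000 random lists matched on expression, and 0.28 after the GC curve. Apoe, Apoa2, Trf, Apoc1 and Ahsg were among the higher ones, and Apob, the structural protein of very-low-density lipoprotein, was the lower one (log2 fold −1.50). Ttr, the transthyretin gene, was 2.27 higher on the log2 scale although its GC content was 46.5%. Among 16 acute phase genes, 6 were higher, 3 lower and 7 not called (9 and 0 under total-count scaling, 1 and 0 after the GC curve). Their median was 0.81, at the 95.9th percentile, within the central 95% of random lists, and 0.26 after the GC curve. The haptoglobin gene Hp read 45.5 and 1512 TPM (log2 fold 4.16), Serpina3n 52.3 and 247 (1.35), ceruloplasmin, Cp, 821 and 675 (−1.32) and C-reactive protein, Crp, 519 and 458 (−1.07). The iron hormone gene Hamp (1208 and 3543 TPM) and Orm1 (767 and 1473) were not called. Iron handling genes as a list had 5 higher, 3 lower and 5 not called of 13 (8 and 1 under total-count scaling, 1 and 1 after the GC curve). Their median was 0.63, at the 96.7th percentile, 0.027 after the GC curve and, with at least 200 counts, above the random range (0.71). The ferritin light chain gene Ftl1 read 33.6 and 2993 TPM (log2 fold 5.63), the ferritin heavy chain gene Fth1 765 and 2147 (0.59, not called) and the lipid peroxidase Gpx4 28.3 and 338 (3.21).

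Major urinary protein genes and female-biased genes lay mostly on the low side under TMM. Of 17 tested Mup genes, 15 were lower in library 2, 0 higher and 2 not called (1 higher and 3 lower under total-count scaling, 1 and 0 after the GC curve). Their median was −1.35, at the 0.03rd percentile. Mup11 (log2 fold −0.29) and Mup13 (0.93) were the exceptions, and Mup8, with 9 counts in library 1 and 0 in library 2, and Mup6, with 4 and 2, fell under the count minimum. Female-biased genes had 15 lower, 3 higher and 8 not called of 26 (3 higher and 4 lower under total-count scaling, 2 and 1 after the GC curve). Their median was −1.05, at the 1.21st percentile. Cyp3a41a (−1.74), Cyp2c40 (−1.13) and Sult2a2 (−1.26) were lower and Hamp2 (1.38) higher. After the GC curve, both medians turned slightly positive, 0.044 for the Mup genes and 0.033 for the female-biased genes, inside the range of random lists. The 22 tested male-biased genes split into 6 higher, 6 lower and 10 not called (7 and 3 under total-count scaling, 2 and 0 after the GC curve). Their median was −0.32, at the 33.7th percentile, and became 0.25 under total-count scaling and 0.0058 after the GC curve. The X inactivation RNAs Xist (−1.66), Jpx (−1.09) and Ftx (−1.35) were all 3 lower under TMM, 1 of 3 under total-count scaling and 0 of 3 after the GC curve. Their median was −1.35, at the 5.05th percentile, and −0.28 after the GC curve. Tsix had 2 and 0 counts.

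Liver lobules carry different hepatocyte programmes near the portal vein and near the central vein, and whole liver holds both. The periportal list exceeded the pericentral list by 1.16 in library 1 and 0.17 in library 2 in median log2(TPM + 0.1) (mean 0.66 ± 0.70, SD), a gap smaller than its technical spread. Periportal genes had 12 higher in library 2, 2 lower and 12 not called of 26 (16 and 0 under total-count scaling, 3 and 0 after the GC curve). Their median was 0.89, at the 99.96th percentile, which the GC curve brought inside the range of random lists (0.19). The urea cycle enzyme gene Ass1 read 296 and 2854 TPM (log2 fold 2.38) and Cyp2f2 133 and 999.5 (2.02), whereas Cps1 (768 and 875 TPM), Arg1 (491 and 920.3), Pck1 (254 and 826) and Pigr (403 and 652) were not called. Pericentral genes had 10 higher, 4 lower and 12 not called of 26 (12 and 0 under total-count scaling, 3 and 1 after the GC curve). Their median was 0.24, at the 95.9th percentile, and 0.125 after the GC curve. Rgn (1616 and 1349 TPM, log2 fold −1.15) was lower, and Cyp2c50 (1568 and 1529), Aldh1a1 (995 and 1047) and Cyp2c37 (931 and 986) were not called. Xenobiotic cytochrome P450 genes had 4 higher, 13 lower and 9 not called of 26 (6 and 0 under total-count scaling, 1 and 0 after the GC curve). Their median was −1.01, at the 5.37th percentile, and turned to 0.11 after the GC curve. Cyp2c29 (−1.11) and Cyp2c70 (1127 and 747 TPM, −1.35) were lower, and the dioxin-inducible Cyp1a1 read 0.29 and 0.27 TPM.

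Metabolic genes were largely detected, with at most 1 member of each list below under 1 TPM in both libraries. Bile acid genes had 7 higher, 7 lower and 12 not called of 26 (9 and 2 under total-count scaling, 2 and 0 after the GC curve). Their median was −0.26, at the 82.0th percentile, and became 0.32 under total-count scaling and 0.14 after the GC curve. The bile acid ligase gene Slc27a5 (145 and 1105 TPM, log2 fold 2.67) and Hsd3b7 (1.38) were higher and Slco1b2 (958 and 526 TPM, −1.72) and Akr1c6 (−1.18) lower. Urea cycle genes had 3 higher, 1 lower and 4 not called of 8 (3 and 0 under total-count scaling, 1 and 0 after the GC curve). Their median was −0.25, at the 68.6th percentile, and became 0.33 and 0.32. Asl (27.8 and 378 TPM, 2.91) was higher and Otc (537 and 373, −1.41) lower. Gluconeogenesis and glycolysis genes had 9 higher, 1 lower and 10 not called of 20 (13 and 0 under total-count scaling, 5 and 1 after the GC curve). Their median was 0.90, at the 99.8th percentile, and 0.36 after the GC curve. Gapdh read 78.6 and 1075 TPM (3.98), while Fbp1 (229 and 756) was not called. Fatty acid and sterol synthesis genes had 10 higher, 5 lower and 10 not called of 25 (13 and 1 under total-count scaling, 2 and 1 after the GC curve). Their median was 0.47, at the 99.3rd percentile, and turned to −0.26 after the GC curve. Hmgcs1 (352 and 299 TPM, −1.12) and Idi1 (334 and 203, −1.62) were lower and Scd1 (750.1 and 716) was not called. Fatty acid oxidation and ketogenesis genes had 8 higher, 0 lower and 16 not called of 24 (14 and 0 under total-count scaling, 2 and 0 after the GC curve). Their median was 0.64, at the 99.7th percentile, and 0.255 after the GC curve. Acaa1b (31.6 and 826 TPM, 3.78) and Acaa2 (98.9 and 663, 1.85) were higher, and Fgf21 had 0 and 11 counts.

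Hepatocyte transcription factor genes had 10 higher, 4 lower and 9 not called of 23 (13 and 0 under total-count scaling, 3 and 6 after the GC curve). Their median was 0.67, at the 98.4th percentile, and turned to −0.47 after the GC curve. DESeq2 size factors gave 9 higher there, and 9 higher for fatty acid and sterol synthesis. The nuclear receptor gene Nr1i3 read 44.8 and 233 TPM (log2 fold 1.28), Creb3l3 20.1 and 156 (1.98), Cebpa 20.9 and 100 (1.37) and Rxra 9.87 and 101 (2.42), while Hnf4a (49.7 and 172) and Nr1h4 (44.3 and 73.1) were not called. Clock genes had 5 higher, 3 lower and 10 not called of 18 (9 and 1 under total-count scaling, 0 and 3 after the GC curve). Their median was 0.42, at the 80.2nd percentile, and turned to −0.31 after the GC curve, below the range of random lists. The clock repressor gene Nr1d1 read 3.08 and 38.4 TPM, 8.02-fold higher in library 2, and its paralog Nr1d2 26.0 and 14.6 (−1.76). Immediate early and heat shock genes had 9 higher, 2 lower and 8 not called of 19 (14 and 0 under total-count scaling, 2 and 2 after the GC curve). Their median was 1.18, at the 97.7th percentile, fell inside the random range with at least 200 counts (0.79) or without the largest member (0.96), and turned to −0.10 after the GC curve. Gadd45g read 0.68 and 87.2 TPM (6.09) and the chaperone gene Hsp90aa1 132 and 71.0 (−1.37), while Hspa8 (427 and 736) and Egr1 (9.45 and 28.1) were not called. Cell cycle genes had 2 higher, 1 lower and 7 not called of 10 (2 and 0 under total-count scaling, 1 and 0 after the GC curve). Their median was −0.65, at the 6.67th percentile, and −0.03 after the GC curve. Pcna read 27.3 and 23.4 TPM and the proliferation marker Mki67 0.09 and 0.08. Nuclear-retained noncoding RNAs had 2 higher, 4 lower and 3 not called of 9 (2 and 1 under total-count scaling, 0 and 0 after the GC curve). Their median was −0.80, at the 13.6th percentile, and −0.20 after the GC curve. Malat1 read 349 and 125 TPM (−1.40) and Neat1 86.9 and 172 (0.16, not called).

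Markers of other liver cells differed in level: no Kupffer, sinusoidal endothelial or stellate marker was under 1 TPM in both libraries, but 4 of 14 cholangiocyte, 10 of 18 lymphocyte and NK cell and 8 of 10 neutrophil markers were. Kupffer cell and macrophage markers had 10 higher, 2 lower and 5 not called of 17 (11 and 0 under total-count scaling, 1 and 0 after the GC curve). Their median was 1.42, at the 98.5th percentile, 0.34 after the GC curve and, with at least 200 counts, inside the random range (1.23). Cd74 read 3.49 and 74.9 TPM (log2 fold 3.55), Clec4f 7.82 and 59.6 (1.73) and Vsig4 38.2 and 28.6 (−1.34). Sinusoidal endothelial markers had 8 higher, 3 lower and 9 not called of 20 (12 and 0 under total-count scaling, 2 and 1 after the GC curve). Their median was 0.78, at the 93.7th percentile. After the GC curve it was 0.2464, at the very edge of the range of random lists (up to 0.2459). Clec4g read 13.8 and 60.3 TPM (1.23) and Mrc1 20.1 and 11.1 (−1.43). Stellate cell and fibroblast markers had 9 higher, 3 lower and 6 not called of 18 (10 and 0 under total-count scaling, 1 and 4 after the GC curve). Their median was 1.19, at the 96.4th percentile, 0.084 after the GC curve and turned to −0.49 with at least 200 counts. Ecm1 read 7.10 and 104 TPM (3.24) and Dcn 121 and 118 (−0.90, not called). Cholangiocyte markers had 3 higher, 2 lower and 6 not called of 11 (6 and 0 under total-count scaling, 0 and 1 after the GC curve). Their median was 0.56, at the 65.9th percentile, and 0.10 after the GC curve. Spp1 was highest, at 45.9 and 58.0 TPM. Lymphocyte and NK cell markers had 4 higher, 3 lower and 3 not called of 10 (6 and 1 under total-count scaling, 0 and 0 after the GC curve). Their median was 1.26, at the 85.7th percentile, and 0.010 after the GC curve. Ighm read 1.85 and 9.15 TPM and Ptprc 3.16 and 2.94. Only Csf3r of the neutrophil markers could be tested. It was higher in library 2 (1.70), also under total-count scaling, but was not called after the GC curve. S100a8 read 2.30 and 1.89 TPM. Erythroid genes were higher in library 2 in 6 of 6 tested under TMM, DESeq2 and total-count scaling, while after the GC curve 3 were called higher and 1 lower. Their median was 2.93, at the 99.9th percentile, and 1.29 after the GC curve. Hbb-bs read 52.4 and 756 TPM (3.40), Hba-a2 75.3 and 772 (2.45) and its near-identical copy Hba-a1 0.68 and 358 (8.03), a split between copies that is uncertain.

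Most listed markers of pancreas, intestine, kidney, fat and muscle were under 1 TPM in both libraries. Of the pancreatic acinar genes only Cela1 was tested (0.86 and 8.28 TPM). It was higher in library 2, also under total-count scaling, but was not called after the GC curve. Prss1, Prss2 and Cpa1 had 0 counts. Intestinal genes had 2 higher, 2 lower and 1 not called of 5 (2 and 1 under total-count scaling, 1 and 1 after the GC curve). Their median was −0.71, at the 28.8th percentile, and turned to 0.12 after the GC curve, to 1.20 with at least 200 counts and to 0.20 without the largest member. Fabp2 read 70.7 and 80.4 TPM, Apoa4 3.06 and 116, and the sucrase gene Sis had 39 counts in library 1 and 0 in library 2, at least 16.3-fold lower against a floor of 3 counts in library 2. Of 2 tested kidney genes, Aqp1 was higher (7.25 and 60.2 TPM) and Kap, an androgen-regulated kidney gene, at least 9.17-fold lower (22 and 0 counts), while Umod had 2 and 0 counts. Both were also called under total-count scaling. Only 1 of these 2 had a GC value, and it was not called after the GC curve. Adipocyte genes had 1 higher, 0 lower and 3 not called of 4. Their median was −0.02, at the 38.7th percentile, and became 0.56 under total-count scaling and 0.595 after the GC curve, where 1 gene was called higher and 1 lower. The carbonic anhydrase gene Car3 read 1483 and 1619 TPM, and Cfd, with 0 and 21 counts, was at least 5.60-fold higher. No skeletal muscle or Y-linked gene reached the count minimum, and Mylpf led the muscle list with 0 and 11 counts. All 15 mitochondrially encoded genes were lower in library 2 under TMM, DESeq2 and total-count scaling, with a median of −2.35 below every random list. After the GC curve 4 were called lower (mt-Co2, mt-Co3, mt-Nd3 and mt-Nd4l) and the median was −0.61. The cytochrome oxidase subunit mt-Co2 had 213637 and 12627 counts (log2 fold −4.40). That value and all 4 calls depend on the uncertain division of reads with nuclear copies. Whether any of the 4 would be called with its reads pooled with those of its copy was not tested. The counts of called genes adjusted over the list alone equalled those adjusted over all genes in 32 of 32 lists with a tested gene. Of the lists, 12 of 29 with at least 3 tested genes lay outside the central 95% of random lists. After the GC curve 10 did so, and 6 did so on the same side in both. Lists of independent genes would give 1.45 by chance. Some lists share genes and some hold near-identical paralogs that share reads, so 1.45 need not hold for them. The endothelial list, counted in the 10, lay at the very edge. The curve turned the sign of the median in 12 of the 29.

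**Figure D4:**
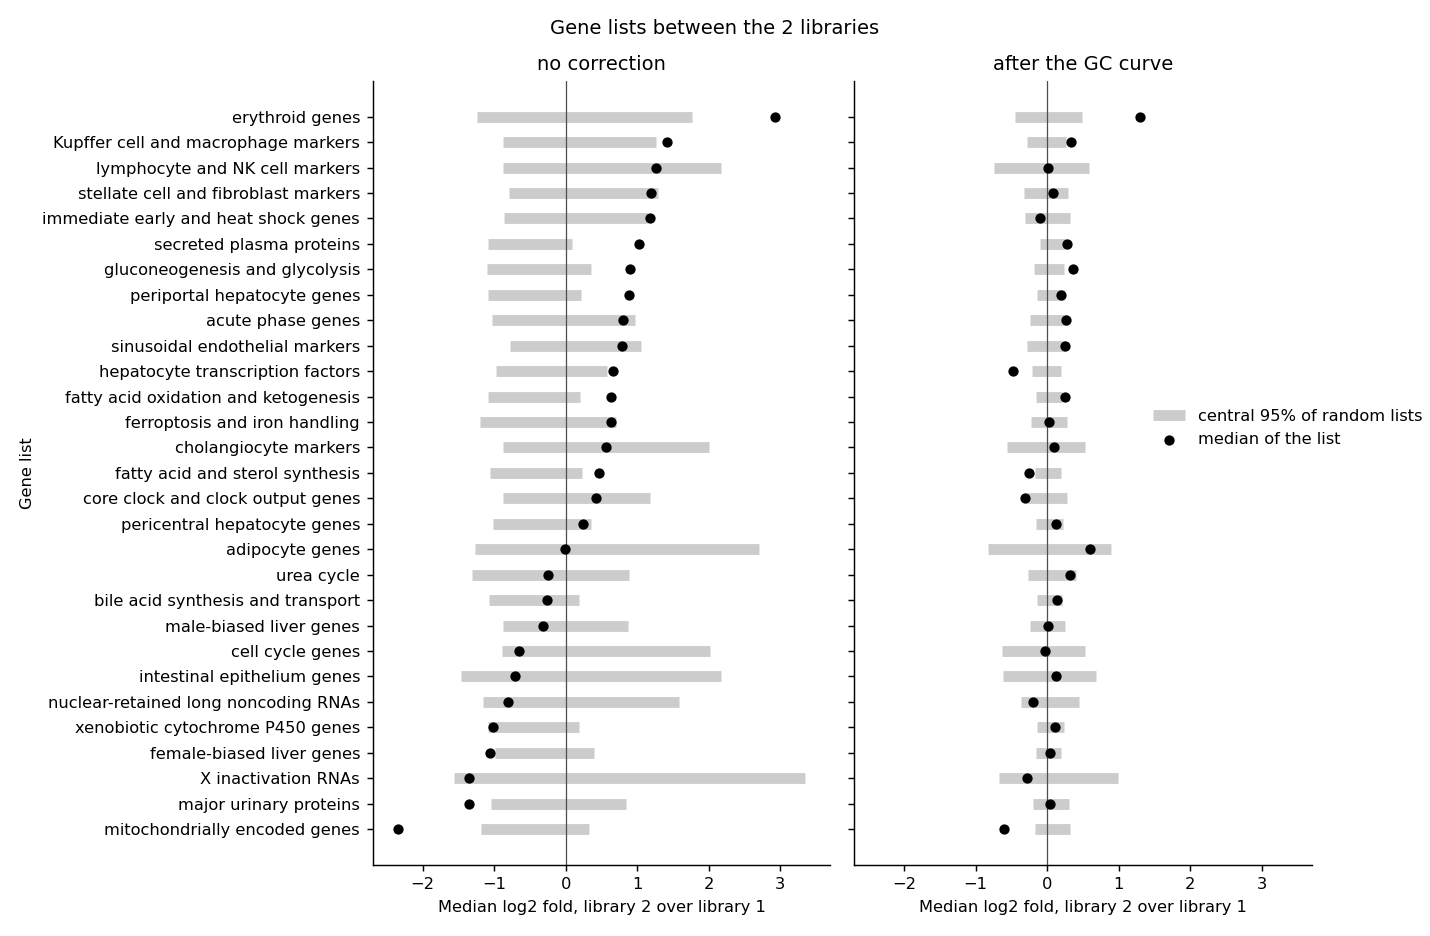
Median log2 fold of library 2 over library 1 (points, TMM scaling) of the 29 fixed gene lists with at least 3 tested genes, with the central 95% of 10000 random lists matched on expression (grey bars), without correction and after the GC curve. Erythroid genes (2.93 and 1.29) and mitochondrially encoded genes (−2.35 and −0.61) lay outside the bars in both panels; the medians of the male-biased, bile acid, urea cycle and adipocyte lists change from negative to positive under total-count scaling.

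The largest single differences, 10 in each direction, had 31 counts or fewer in the lower library. Rpl36, a ribosomal protein gene (ENSMUSG00000057863.5, chromosome 17, 56613416 to 56614243, plus strand), had 0 counts in library 1 and 1348 in library 2, at least 359-fold higher against a floor of 3 counts in library 1. Bcl9l, a Wnt pathway coactivator gene, had 0 and 765 counts (at least 204-fold), the histone gene Hist2h2aa2 0 and 622 (at least 166-fold), Gm20390 0 and 537 (at least 143-fold), the pseudogene Rpl27-ps3 0 and 441 (at least 118-fold), the noncoding RNA Gm26917 0 and 410 (at least 109-fold), the pseudogene Gm12481 0 and 267 (at least 71.2-fold) and the thiouridylase gene Ctu2 0 and 204 (at least 54.4-fold). The tight junction gene Cldn3 had 1 and 1120 counts (log2 fold 9.22, 7.33 to 15.1) and Abhd17a 1 and 698 (8.54, 6.64 to 14.4). In the other direction, Gm28439, a nuclear copy of mitochondrial sequence (ENSMUSG00000100131.1, chromosome 1, 24611535 to 24612410, minus strand), had 65378 counts in library 1 and 31 in library 2 (log2 fold −11.34, −11.92 to −10.86). The pseudogene Gm4294 had 213 and 0 counts (at least 88.8-fold lower), Gm28037 133 and 0 (at least 55.5-fold), Rpl38-ps2 86 and 0 (at least 35.9-fold), Gm7206 52 and 0 (at least 21.7-fold) and Gm15452 36 and 0 (at least 15.0-fold). Gm20547 (790 and 9 counts), Gm20708 (742 and 22), Gm6829 (66 and 2, log2 fold −5.06, −8.44 to −3.46) and Gm15899 (67 and 3, −4.59, −7.12 to −3.19) completed the 10 named in this direction. Pseudogenes and predicted genes can share reads with an expressed gene of similar or overlapping sequence, so the values of these loci are uncertain. All counts are estimates that divide shared reads, so a 0 can also come from that division. The bounds, those of coding genes such as Rpl36 and Hist2h2aa2 included, cover counting error only.

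The transcript that led a gene often differed between the libraries. Of 3520 genes with at least 2 annotated transcripts and a mean TPM of at least 10, 2402 (68.2%, exact binomial 95% interval 66.7 to 69.8%) had the same leading transcript in both libraries and 1118 another one. Among the 10 largest changes of share, the adenylate kinase gene Ak4 moved from 100% in Ak4-202 to 70.6% in Ak4-201, a transcript of nearly the same length, and the thioesterase gene Lypla2 from 100% in Lypla2-202 to 86.9% in Lypla2-201. The ribosomal protein gene Rps16 went from 100% in a retained-intron transcript, Rps16-203, to 99.4% in the coding Rps16-201, and Mrps12 from 100% in the noncoding Mrps12-203 to 97.0% in the coding Mrps12-201. Nxt2, Mapk3, Rpl38, Atf5 and Bsg changed leader as well. Mapk3 went from 57.1% in Mapk3-203 to 100% in Mapk3-202 and Bsg from 99.8% in Bsg-202 to 97.8% in Bsg-205. The minimum of 10 applied to the mean TPM. Lypla2 read 0.59 TPM in library 1, under the detection level, and 41.7 in library 2, and Mapk3 2.06 and 21.7. Their library 1 shares therefore rest on low levels and are uncertain. Among abundant genes picked after their values were seen, Apoe was led by Apoe-206 with 98.4% in library 1 and by the processed transcript Apoe-202 with 59.1% in library 2, and Apoa1 by Apoa1-202 with 75% and by Apoa1-201 with 97.6%. Where the leader changed and both GC contents were known, the library 2 leader had the higher GC in 826 of 1023 genes (80.7%, 78.2 to 83.1%), and it was the shorter one in 252 of 1118 (22.5%, 20.1 to 25.1%). Leading transcripts were protein-coding for 82.1% of genes in library 1 and 92.0% in library 2.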

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

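The GC curve and the analysis without mitochondrial genes and their copies were chosen only after the results were seen; the other alternatives were planned. No paired analysis was possible because there is 1 group. Of the alternatives to the main results, 45 left the value within its spread or within 1.5 times the count and 20 moved it. Of those to the medians of single lists, 116 kept direction and side of the random range, 4 kept the direction and fell inside it, 2 kept the direction and left it, and 19 reversed. Under DESeq2 and total-count scaling a list and its random lists shift by the same amount. There the side of the range could not change, and only the direction was tested. With at least 200 counts, cell cycle, adipocyte, lymphocyte and X inactivation lists had too few genes.

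Subtracting the GC curve lowered the median size of the log2 fold from 1.15 to 0.37 and the called genes from 7165 (6832 with a GC value) to 1708. It turned the medians of 12 of 29 lists: major urinary protein (0.044), female-biased (0.033), male-biased (0.0058), xenobiotic P450 (0.11), bile acid (0.14), urea cycle (0.32), intestinal (0.12), adipocyte (0.595), fatty acid and sterol synthesis (−0.26), hepatocyte transcription factors (−0.47), clock (−0.31) and immediate early genes (−0.10). Removing the trend with GC also brought the periportal list (0.19) inside the random range. It took the endothelial list (0.2464) just past the edge of that range (0.2459). Total-count scaling turned the male-biased (0.25), bile acid (0.32), urea cycle (0.33) and adipocyte (0.56) medians, at least 200 counts the stellate (−0.49) and intestinal (1.20) ones, and leaving out the largest member the intestinal one (0.20). The median size of the fold was 0.996 (total-count scaling), 0.965 (TPM ratio), 1.30 (no count minimum), 1.07 (summed count of at least 200) and 1.13 (prior count 2). With at least 200 counts 4732 genes were called of 8820 tested, because fewer were tested. The coefficient of variation was 76.4% with DESeq2 size factors, 74.4% with at least 200 counts, 76.0% for protein-coding genes and 76.4% without mitochondrial genes and copies. Pearson's r was 0.818 with pseudocount 1, 0.934 with no filter, 0.718 with at least 200 counts and 0.817 with posterior mean TPM. The same isoform led in 70.2% of genes at a TPM of at least 100 and in 71.1% where a leading share passed 50%. At a TPM of at least 5, 4881 genes were detected in both libraries. Immediate early genes entered the random range with at least 200 counts (0.79) and without their largest member (0.96), and the Kupffer list with at least 200 counts (1.23), while iron handling left it there (0.71). The sex list gap without members under 1 TPM was 1.93. Except where the alternative changes the genes counted, the cause was not tested.

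Leaving out 1 library gave 9089 to 11371 detected genes, 27.9 to 52.5% of TPM in the top 10, 6.54 to 19.95% in plasma proteins, a sex list gap of 2.54 to 3.25 and a zonation gap of 0.17 to 1.16. With n = 2 a mean always stays within 1 SD when a library is left out, so this says nothing about stability. Depth limits genes near 0 counts, where only bounds are given.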

Other observations

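The tests of non-hepatocyte cells, of mitochondrial transcripts taking depth, of pooled mitochondrial reads and of isoforms of nearly equal length, and the use of intervals in reading every test, were chosen only after the results were seen, as were the genes named here. The other tests were written before they were run. Those that use the GC curve rest on a step that was not in the plan. No biological explanation given by the design was tested, because it has 1 group and 1 animal; the tests on cell types, time of day, animal and nuclear RNA concern the material behind the libraries.

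Some genes departed from the trend with GC content, in both directions. Ttr, the transthyretin gene, rose from a log2 fold of 2.27 to 2.90 after the GC curve, and Cux2, a female-biased transcription factor gene with 7 and 77 counts, from 3.05 to 3.39. Ftl1 kept 2.49 of 5.63, the haptoglobin gene Hp 1.75 of 4.16, Gapdh 1.58 of 3.98, the serine dehydratase gene Sds 2.65 of 5.74 and the ammonium transporter gene Rhbg 3.60 of 6.29. Among globin genes, Hbb-bs (2.06), Hbb-bt (3.48) and Hba-a1 (5.20) remained higher in library 2 and Hba-a2 (−0.23) was no longer called, while the erythroid factor gene Klf1 went from 2.04 to −2.13 and was called lower; Hba-a1 and Hba-a2 are near-identical. Fabp1, not called before, was called higher after the curve (1.58). Sap18b (10 and 352 counts) stood at 4.75 before and 5.16 after.

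Of the hepatocyte transcription factor genes with a GC value, 22 in number, 6 were called lower and 3 higher after the curve, the latter including Nr1h3 (1.79) and Nr0b2 (1.72). Among the lower ones, Cebpb moved from a log2 fold of 0.39 to −5.77, Cebpa from 1.37 to −3.32, Foxa1 from −0.96 to −2.56, Foxa2 from 0.14 to −2.54 and Tbx3 from −0.43 to −1.65. The clock output gene Dbp moved from 1.43 to −2.91, the retinol carrier gene Rbp4 from 0.29 to −1.35 and Smim10l1 from −1.87 to −5.79. These values rest on subtracting a curve that is steep at high GC, and Cebpb has 67.2% GC, while 411 of 12128 genes had at least 60%.

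The libraries of 1 animal differed by far more than counting error. A further curve on transcript length left 92.3% (95% interval 91.0 to 93.5%) as many genes called as the GC curve alone. This value met the bound set against length, but only for calls beyond the GC curve. A curve on length alone was not tried, so a length effect shared with GC cannot be told apart from GC. After the GC curve, length and the fold correlated across genes with a rho of −0.23. Mitochondrial genes and their copies took 35.3% of counts in library 1 and 11.1% in library 2. Lost depth would shift all nuclear genes alike, a shift that TMM removes, so it could not be the whole cause. The folds of 12704 genes other than mitochondrial genes and their copies had an interquartile range of 2.559 (2.498 to 2.611). That range holds the trend with GC, which had been seen before this test was chosen. The first test of lost depth, a count of called genes without mitochondrial genes and their copies, was fixed in advance by the scaling and decided nothing. A different share of non-hepatocyte cells would keep hepatocyte genes in fixed ratios, so it could not be the whole cause, since the folds of the plasma protein genes had an interquartile range of 1.92 (1.22 to 2.52). That range holds the trend with GC, and after the curve it was 0.63 (0.404 to 0.905), between the bounds, so a different cell share in the part beyond the curve stays open. The first test of that explanation, on marker medians after the curve, met neither of its bounds. Kupffer (0.34) lay above the range of random lists, endothelial (0.25) at its upper edge and stellate (0.08) inside it. Erythroid genes (1.29) lay above their range (up to 0.487), with 3 of 6 called higher and 1 lower. Cholangiocyte (0.10) and lymphocyte (0.010) markers lay inside theirs. GC content may account for most of the difference: 25% (24.0 to 26.0%) as many genes were called after the curve, so a part of the difference lay beyond it. The intervals of 25% and of 92.3% both treat the later calls as a subset of the earlier ones. Fabp1, among others, was called only after the GC curve, so these intervals do not measure the spread of the ratios.

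Another time of day or another animal behind 1 library stays open. The size of the clock genes' folds after the GC curve lay at the 81.8th percentile of random lists, under the bound set against the explanation. Its bootstrap interval of 24.5 to 99.7 was too wide to decide, and without the interval that bound would have been met. Clock genes could not exclude another animal taken at the same time of day, whatever the percentile. The signed median of the clock genes after the curve, −0.31, lay at the 1.82nd percentile. The labels give 1 animal for both libraries.

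The smaller mitochondrial share of library 2 went partly with GC content. The 13 mitochondrially encoded protein-coding genes had a median log2 fold of −2.47 against −1.86 on the curve of nuclear genes at their GC contents, a difference of −0.61 (−1.23 to −0.26) that lay between the bounds set for and against GC as the cause, so whether it may be the whole cause stays open. Pooling the reads of 24 mitochondrial genes and nuclear copies, which removes the division of reads between them, left −0.48. A higher share of nuclear RNA in library 2 would have raised nuclear-retained RNAs by over 0.5, whereas their median after the curve was −0.20 (−0.44 to 0.20), with Malat1 at −0.12, Xist at −0.28, Neat1 at −0.33, Gas5 at 0.20 and, the highest, Gm26917 at 2.57 (0 and 410 counts, not called after the curve).

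Leading isoforms also differed with GC content and length. The isoform leading in library 2 had the higher GC in 80.7% (78.2 to 83.1%) of changed genes and was the shorter one in 22.5% (20.1 to 25.1%), so both GC and length may contribute. Among 144 genes whose leaders differed in length by at most 5%, 107 (74.3%, 66.4 to 81.2%) had the higher GC in library 2, and among 197 whose library 2 leader had the lower GC, 147 (74.6%, 67.9 to 80.5%) had the longer one there. Few reads as the cause would have brought the share of changed genes at a TPM of at least 100 under 50% of the share at 10, but it was 93.9% (82.5 to 106%) of it.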
